A study of Mus musculus with 68 samples.

How the data were processed

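The study measured transcript levels by RNA-seq of total RNA in 68 mouse libraries. Per the labels, libraries were made with NuGEN Ovation RNA-seq V2 and Ultralow kits. For 66 libraries, whole brain among them, the labels describe cells sorted into Trizol and extraction with phenol and chloroform. The 2 named brain endothelial came from forebrain of adult male mice carrying a tdTomato reporter and a tamoxifen-induced Cre under VE-Cadherin, with papain, collagenase and dispase digestion, myelin removal, sorting, Trizol and a Qiagen column. Brain vascular cells, which carry the description of the organ libraries, were run in place of brain endothelial cells. In that setting the described preparation is the same, but the sort differs. The submitters' processing notes name TopHat2 2.0.13, featureCounts, Subread and the mm9 build, without saying which step each was used for. The authors deposited 1 table with a CPM column per library (reads scaled by the authors so that each column sums to 1000000), log2 columns that are the authors' log2 fold changes, and other columns that hold the authors' class marks for genes, per the file headers. The table has 37991 lines with 3401 repeated symbols, so genes were kept apart by identifier and a repeated symbol stayed with the identifier of highest mean. Of the symbols, 25 had been turned into dates by a spreadsheet and were repaired from their identifiers. A list of 32919 identifiers and names made for a later build was used for names and for no coordinates.

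Whole reads were recovered from the CPM values by taking the smallest nonzero value of each library as 1 read. Of 1374704 nonzero values, 100% were whole multiples within a tolerance of 0.001. Depth by this measure was 18.8 to 38.8 M reads per library, with a median of 27.3 M. Libraries held 15153 to 24631 genes with a read, and the 2 mitochondrial rRNA genes took 12.2 to 51.8% of the reads. Because the unit of the table is CPM and not counts, the count version of the planned design was not used, and the version for normalized values was.

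Groups were taken from the labels, and the comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. CPM values were tested with limma 3.58.1 with a trend in R 4.3.3, on log2(CPM + 1). Genes needed over 1 CPM in at least 3 libraries of a model (epilepsy, EAE and stroke) or 2 (TBI and healthy groups). All groups of a model shared 1 fit, p-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes were called at an adjusted p under 0.05. Each injured group was compared with its own control, and each stage directly with the one before it. Brain endothelial cells were compared with each of 4 organs, their mean, whole brain and brain vascular cells. Brain-enriched and brain-depleted genes passed against each of the 4 organs with a log2 fold beyond 1 in the same direction. Genes shared by models were those called in the same direction in 3 or more models, each with separate controls, and an F test in limma asked whether the log2 fold differed between the 4 models.

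The 22 lists of biology covered barrier junctions, barrier transporters, the Wnt beta-catenin pathway, caveolae and vesicle diaphragms, leukocyte adhesion, NF-kB and cytokine targets, interferon response, MHC classes I and II, angiogenesis, extracellular matrix, cell cycle, immediate early genes, hypoxia and glycolysis, glucocorticoid targets, NRF2 targets, ribosomal proteins, the endothelium of liver, heart, lung and kidney, and Hox genes. The 14 marker lists covered endothelial, mural, fibroblast, astrocyte, neuron, oligodendrocyte, microglial, neutrophil, lymphocyte, red blood, liver, heart muscle, kidney tubule and lung epithelial cells. Each list was tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with p adjusted over the lists of the comparison. Counts of members used the calls over all genes, and a second adjustment over the list alone. Named genes were the 5 with the largest rise and the 5 with the largest fall among called genes of upper-half expression whose libraries did not overlap, up to 3 members of each list with the smallest adjusted p, 8 barrier and endothelial genes, and the 6 genes shared by models at a stage with the largest mean change. From these the text prints a selection, and the other genes raised in all 4 models at the acute stage were chosen after their values were seen.

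Alternatives fixed before the data were examined were quantile normalization, no filter, limma without a trend, a pseudocount of 0.1, the replicate number as a replicate block, a fit of only the 2 compared groups, all 4 models in 1 fit, pooled TBI controls, brain vascular in place of brain endothelial cells, lists without markers of other cells or built on brain vascular cells, a log2 fold beyond 0 in place of 1, and each library left out in turn. Chosen after seeing the data were a quasi-likelihood test of edgeR 4.0.16 with TMM scaling on the recovered reads, scaling without mitochondrial rRNA, the mural marker level as a covariate, leaving out the 3 acute-stage TBI libraries with low mural levels, and these settings for the stage contrasts. Random regroupings used 10 splits of 6 libraries or 100 permutations of labels within models, with seed 1. The real grouping was counted as 1 of the 10 splits and as 1 of the 100 permutations. The method was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold: at the subacute stage 71 and 96% were called for epilepsy, 31 and 93% for EAE, 82 and 100% for stroke and 46 and 98% for TBI, and 3 and 28% for brain against heart (n = 2), with 3 to 12 unchanged genes called. In simulated data the test of a difference between models called 57 of 60 genes changed in 1 model and 18 genes that did not differ. The rule for brain-enriched and brain-depleted genes recovered 12 of 100 simulated genes raised and 8 of 100 lowered by 2- or 4-fold, so it can miss many genes with changes of this size. The authors' log2 columns were compared with the fitted values gene by gene and were not used for any test.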

Results

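The series held 68 mouse RNA-seq libraries in 25 groups, made to compare endothelial cells of healthy organs and endothelial cells of the central nervous system after injury. Healthy groups were endothelial cells sorted from brain, heart, kidney, lung and liver and cells named brain vascular (n = 2 each), with whole brain (n = 4). The injury groups were endothelial cells of brain after epilepsy, stroke by middle cerebral artery occlusion and traumatic brain injury (TBI), and of spinal cord in experimental autoimmune encephalomyelitis (EAE). Each model had control, acute, subacute and chronic groups of n = 3, and TBI had its own control group per stage, with n = 2 at the subacute and chronic stages. Per the labels, the 2 brain endothelial libraries came from tamoxifen-treated reporter mice by papain, collagenase and dispase digestion with myelin removal, and the other 66 carry another, shorter description. Organ and preparation are therefore confounded in every comparison of brain endothelial cells with heart, kidney, lung and liver, and sort and preparation in those with whole brain and brain vascular cells. Levels are mean CPM ± SD over libraries, and log2 folds are given ± SE. Mean levels of the endothelial marker list lay at 8.51 to 9.27 log2 units in every sorted group and at 3.20 in whole brain. Whether replicates came from separate animals was not stated in the labels, so p-values measure the spread between these libraries.

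Healthy brain endothelial cells carried higher levels of blood-brain barrier transporters than endothelial cells of the other organs. Spock2, a secreted proteoglycan gene, stood at 8714 ± 402 CPM in brain and at 29.9 ± 3.97 in heart (log2 fold against the mean of the 4 organs 9.52 ± 0.38, limma adjusted p = 4.27e-10, n = 2 per organ). Slco1a4, an organic anion transporter, reached 3021 ± 694 CPM (8.93 ± 0.21). Slco1c1, which carries thyroxine, reached 1404 ± 151 CPM (8.28 ± 0.27). Slc22a8 (8.71 ± 0.29), the glutamine carrier Slc38a3 (7.72 ± 0.41), the lysophospholipid carrier Mfsd2a (8.07 ± 0.30), the efflux pump Abcb1a (6.90 ± 0.23) and the glucose carrier Slc2a1 (4825 ± 1787 CPM, 6.84 ± 0.28) were higher as well. All 23 measured members of the transporter list were higher than the mean of the 4 organs (median log2 fold 5.59, camera adjusted p = 1.78e-36 and 0.0283 with an estimated correlation). Wnt beta-catenin pathway genes were higher in 15 of 18 (16 adjusted over the list alone, median 3.57, adjusted p = 0.0531 with an estimated correlation). Among them Lef1, a transcription factor of this pathway, stood at 786 ± 120 CPM in brain, 50.4 ± 3.46 in kidney and 0.59 ± 0.38 in heart, and Foxf2 at 188 ± 39.7 CPM (7.15 ± 0.30). Barrier junction genes were higher in 8 of 12 and lower in 0 (8 and 1 adjusted over the list alone, median 1.33, adjusted p = 0.134 with an estimated correlation). Occludin, Ocln, was higher by 5.33 ± 0.27 and Lsr by 4.88 ± 0.35. Claudin 5, Cldn5, stood at 474 ± 346 CPM in brain and 533 ± 245 in lung (1.39 ± 0.46, adjusted p = 0.0344). The pan-endothelial genes Pecam1 (1242 ± 29.3 CPM, -0.04 ± 0.20, adjusted p = 0.937) and Cdh5 (1221 ± 138 CPM, -0.52 ± 0.21, adjusted p = 0.0808) did not pass the test.

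Among the genes lowest in brain endothelial cells against the other organs were Aqp1, Cd36, Gpihbp1 and Plvap. The water channel Aqp1 stood at 0.444 ± 0.628 CPM in brain and 2904 ± 220 in liver (log2 fold against the mean of the 4 organs -9.62 ± 0.34, limma adjusted p = 1.65e-10). The fatty acid carrier Cd36 stood at 0.975 ± 1.00 CPM in brain and 1912 ± 77.3 in heart (-8.92 ± 0.26). Fabp4 (-8.58 ± 0.28), Igfbp5 (-8.23 ± 0.41), the endothelin receptor Ednrb (-8.08 ± 0.30) and Slc43a3 (-7.50 ± 0.22) were lower too. Gpihbp1, which anchors lipoprotein lipase on capillaries, was at 0 in both brain libraries and at 1332 ± 135 CPM in liver. Plvap, the diaphragm protein of fenestrated vessels, stood at 1.66 ± 2.35 CPM in brain and 1013 ± 128 in kidney (-7.01 ± 0.44). The caveolae and vesicle diaphragm list had 3 lower members of 10 (median -0.24, adjusted p = 0.289 by camera). The 7 measured MHC class II genes were all lower (median -4.43, adjusted p = 0.288 with an estimated correlation), for example Cd74 (-5.94 ± 0.57) and H2-Aa (-6.24 ± 0.58). MHC class I genes were lower in 7 of 11 (8 adjusted over the list alone, adjusted p = 0.489 with an estimated correlation). Leukocyte adhesion genes were lower in 7 of 10 (7 lower and 1 higher adjusted over the list alone, 0.288 as the adjusted p with an estimated correlation), with Vcam1 at 43.1 ± 29.8 CPM (-3.28 ± 0.50) and the selectin Selp at 0 in both brain libraries. Matrix genes were lower in 24 of 32 and higher in 3 (median -2.02, adjusted p = 0.288 with an estimated correlation). Biglycan, Bgn, was lower by -4.05 ± 0.24, and fibronectin, Fn1, was higher (2172 ± 110 CPM, 4.06 ± 0.27). Markers of macrophages moved with these groups: 14 of 17 were lower in brain (15 adjusted over the list alone, adjusted p = 0.244 with an estimated correlation), with mean levels of 0.68 log2 units in brain, 4.08 in lung and 4.73 in liver.

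Many members of the endothelial lists of other organs were lower in brain. All 9 liver sinusoidal genes (median -3.91, adjusted p = 0.0413 with an estimated correlation), 7 of 8 heart capillary genes (median -4.47, adjusted p = 0.0380 with an estimated correlation) and all 19 Hox genes (median -1.55, adjusted p = 0.0666 with an estimated correlation) were lower. Lyve1 was lower by -6.68 ± 0.30, while Gata4, Hoxa5, Hoxb4 and Hoxb5 were at 0 in both brain libraries. Lung capillary genes were lower in 7 of 10 and higher in 2 (adjusted p = 0.476 with an estimated correlation), the higher ones including carbonic anhydrase 4, Car4, at 439 ± 30.0 CPM (4.66 ± 0.31). Kidney endothelial genes were lower in 4 of 6 and higher in 1 (adjusted p = 0.489 with an estimated correlation), and the higher one was tissue plasminogen activator, Plat (2.99 ± 0.21). Cell cycle genes were lower in 15 of 26 and higher in 1 (adjusted p = 0.453 with an estimated correlation), with Mki67 at -3.72 ± 0.42. NF-kB and cytokine targets were lower in 12 of 21 (13 lower and 1 higher adjusted over the list alone, adjusted p = 0.489 with an estimated correlation). Ribosomal protein genes were lower in 12 of 26 (18 lower and 1 higher adjusted over the list alone, adjusted p = 0.578 with an estimated correlation), for example Rpl4 (-1.29 ± 0.23). Immediate early genes were higher in 5 of 16 (adjusted p = 0.489 with an estimated correlation). Jun was among them at 1.32 ± 0.30, and at -0.41 with brain vascular cells in place of brain endothelial cells. Angiogenesis genes were higher in 3 and lower in 10 of 22 (adjusted p = 0.670 with an estimated correlation), with the receptor Flt1 higher by 2.78 ± 0.20. Camera found no shift of the interferon (3 higher and 7 lower of 25), hypoxia and glycolysis (4 and 7 of 17), glucocorticoid (3 and 3 of 15) or NRF2 (2 and 5 of 10, median -0.61 and mean 0.01) lists. Of 18141 genes, 2003 were higher and 3734 lower than the mean of the 4 organs (2840 and 2820 with edgeR on recovered reads, 3188 and 3072 with quantile normalization). The median over all genes was -0.14 and became 0.04 with quantile normalization. Against each organ alone, higher and lower counts were 1740 and 2435 for heart (2587 and 2436 with quantile normalization), 938 and 2683 for kidney (1726 and 1831, 1393 and 2046 with edgeR), 1274 and 3168 for lung (2649 and 2471) and 2745 and 3029 for liver. Against all 4 organs at once with a log2 fold beyond 1, 434 genes were enriched and 670 depleted in brain. Brain endothelial library 1 had the fewest reads (18.78 M) and the fewest genes with a read (15153) of all libraries. Library 2 had 21.39 M reads and 18144 genes, so depleted calls and levels of 0 may partly reflect low detection in library 1. Without brain endothelial library 2, 846 were enriched and 1225 depleted, and without library 1, 431 were depleted and 3280 genes passed against the mean of the 4 organs. The authors' deposited class marks held 518 barrier-enriched and 1399 peripheral-enriched genes, of which 370 and 575 were shared with these.

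**Figure D1:**
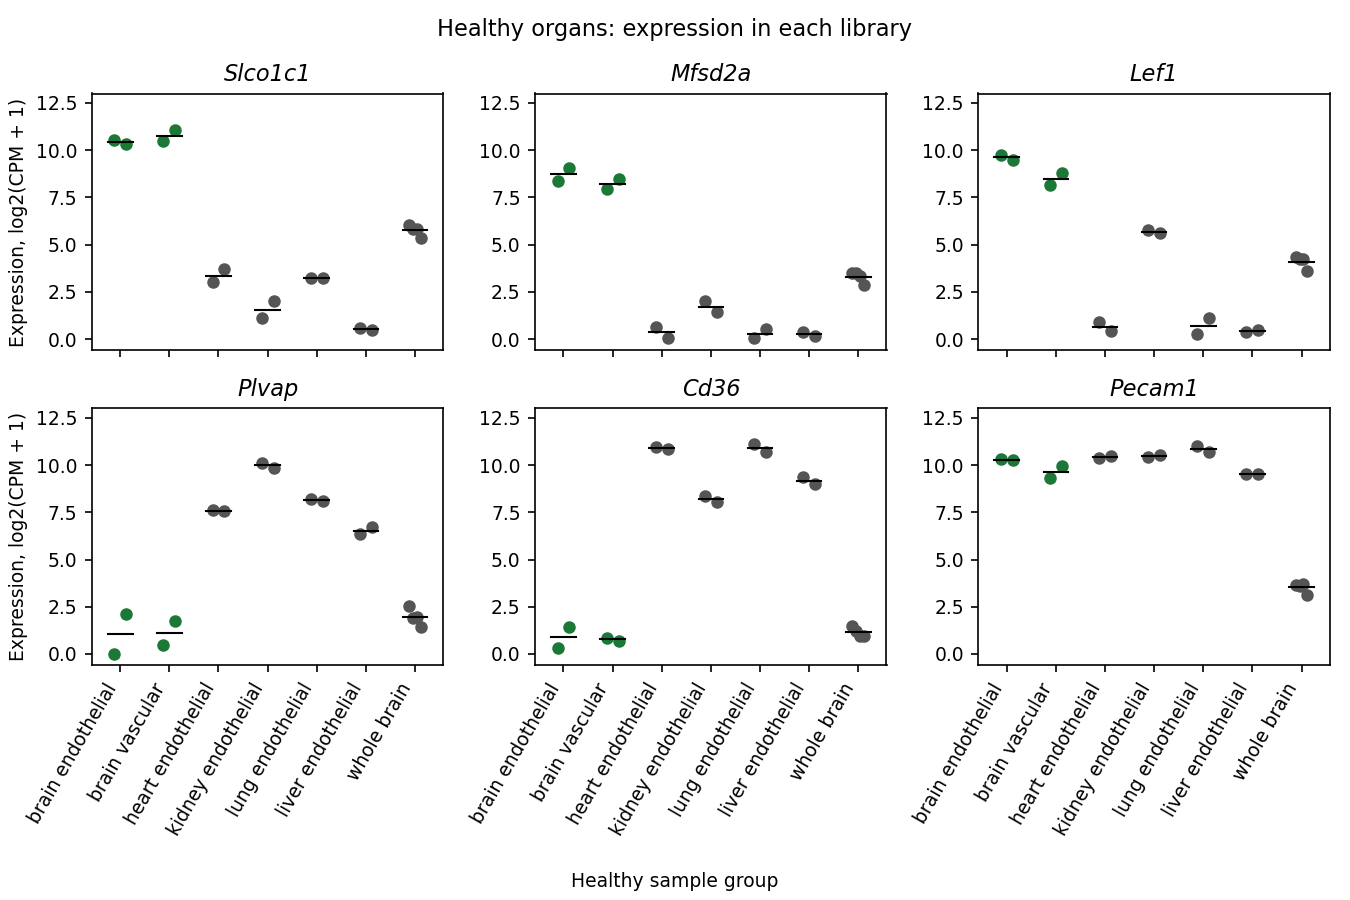
Levels of Slco1c1, Mfsd2a, Lef1, Plvap, Cd36 and Pecam1 in the 7 healthy groups, as log2(CPM + 1) on the vertical axis, with 1 point per library (n = 2, whole brain n = 4), a line at the group mean and brain groups in green. Slco1c1 stood at 1404 CPM in brain endothelial cells and 9.55 in heart, and Cd36 at 0.975 and 1912.

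Endothelial genes were high and neural genes low in sorted brain endothelial cells against whole brain. All 16 endothelial markers (median log2 fold 6.12), all 12 junction, 23 transporter and 18 Wnt pathway genes were higher, and all 12 neuron (median -7.24) and 11 oligodendrocyte markers were lower. The adjusted p with an estimated correlation was 0.114 for each of these 6 lists. Astrocyte markers were lower in 10 of 11 (0.170 as that adjusted p) and microglia and macrophage markers in 16 of 17 (0.462 as that adjusted p). The brain vascular libraries carry the source name brain endothelial cells in the labels, which do not say how this sort differed from the other. They had higher mural markers, genes of pericytes and smooth muscle, in 14 of 16 (15 adjusted over the list alone, median 3.86, adjusted p = 0.0210 with an estimated correlation). Rgs5 stood at 2858 ± 749 against 603 ± 70.0 CPM and Vtn at 764 ± 36.5 against 29.8 ± 16.9. The mean mural level was 6.36 ± 0.01 log2 units in brain vascular cells, 2.87 ± 0.05 in brain endothelial cells and 4.65 to 6.44 in the injury groups. Microglia and macrophage markers lay at 0.68 in brain endothelial cells and at 0.81 to 3.79 in the injury groups. Changes in the injury groups can therefore not be assigned to endothelial cells alone. In the limma test against whole brain 4562 genes were higher and 5913 lower (6339 and 5162 with quantile normalization, 3550 and 8586 with mitochondrial rRNA left out before scaling). The median over all genes was -0.11, 0.16 and -0.55 in the same order. Between brain vascular and endothelial cells 748 were higher and 661 lower (1668 and 552 with mitochondrial rRNA left out). That count of 1409 became 384 and 926 without vascular library 1 or 2 and 598 and 3435 without endothelial library 1 or 2.

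After acute epilepsy 20 of 21 NF-kB and cytokine targets rose and 17 of 23 barrier transporters fell in the sorted brain cells (adjusted p = 0.0839 and 0.243 with an estimated correlation). The urokinase receptor Plaur rose from 51.5 ± 24.99 to 749 ± 133 CPM (log2 fold 3.92 ± 0.23, limma adjusted p = 3.14e-08, n = 3 per group). The metalloproteinases Adamts9 (688 ± 42.2 against 51.5 ± 10.4 CPM, 3.73 ± 0.20) and Adamts4 (3.41 ± 0.27), the tubulin Tubb6 (3.88 ± 0.26) and the iron-binding lipocalin Lcn2 (4.01 ± 0.77) rose. Angpt2, a destabilizer of vessels, rose by 2.78 ± 0.24, and its receptor Tek fell to 296 ± 5.52 from 749 ± 10.6 CPM (-1.34 ± 0.11). Tnfsf10 (-3.55 ± 0.21), the Wnt pathway gene Tnfrsf19 (-3.46 ± 0.21), Tril (-3.45 ± 0.23), Fut8 (-2.80 ± 0.19) and Tet1 (-2.66 ± 0.30) fell. NF-kB and cytokine targets had a median of 1.27 (camera adjusted p = 1.1e-14), for example Csf3 (2.88 ± 0.32), Nfkb2 (1.61 ± 0.17) and Il4ra (1.47 ± 0.17). Glucocorticoid targets rose in 9 of 15 and fell in 0 (median 1.64, adjusted p = 0.0839 with an estimated correlation), with the metallothioneins Mt2 (664 ± 230 against 64.6 ± 15.8 CPM, 3.31 ± 0.23) and Mt1 (1.81 ± 0.16). Matrix genes rose in 10 and fell in 3 of 30 (adjusted p = 0.0839 with an estimated correlation). Of the transporters 3 rose (median of the list -0.97). The zinc carrier Slc39a10 fell from 1733 ± 106 to 346 ± 10.6 CPM (-2.32 ± 0.13), the transferrin receptor Tfrc by -1.80 ± 0.14 and Abcb1a by -0.50 ± 0.12, while Slc2a1 rose to 13070 ± 1073 from 6248 ± 2240 CPM (1.12 ± 0.23). Wnt pathway genes fell in 12 and rose in 1 of 18 (adjusted p = 0.559 with an estimated correlation), including Apcdd1 (-1.57 ± 0.11) and Fzd6 (-1.44 ± 0.13). Interferon response genes fell in 13 of 24 (adjusted p = 0.620 with an estimated correlation). Of 12 junction genes 3 rose and 3 fell (median 0.11, and -0.08 with quantile normalization), with Cdh5 at 1.32 ± 0.15 and Cldn5 at -0.46 ± 0.15. Neutrophil markers rose in 4 of 6 (adjusted p = 0.559 with an estimated correlation). Mfsd2a stood at 314 ± 12.53 against 309 ± 80.8 CPM and Vcam1 at 77.7 ± 16.0 against 137 ± 54.1 CPM, and neither passed the test. In all, 1587 genes were higher and 4247 lower of 13740, or 27.2% higher. Counts were 2559 and 3122 with edgeR, 2471 and 2775 with quantile normalization and 1377 and 5014 with mitochondrial rRNA left out. The median over all genes was -0.22, and -0.01 with quantile normalization.

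At the subacute stage of epilepsy cell division genes rose together. Topoisomerase Top2a rose from 0.513 ± 0.253 to 58.0 ± 13.4 CPM (5.27 ± 0.29, limma adjusted p = 8.18e-08), with Mki67 (5.02 ± 0.34) and Tpx2 (3.73 ± 0.30). Cell cycle genes rose in 25 of 26 and fell in 1 (median 2.00, adjusted p = 0.0386 with an estimated correlation). Matrix genes rose in 17 of 30 (21 rose and 1 fell adjusted over the list alone, median 0.82, adjusted p = 0.0386 with an estimated correlation), with Timp1 (3.45 ± 0.26) and Spp1 (4.23 ± 0.35). Interferon response genes rose in 17 of 24 (median 0.70, adjusted p = 0.231 with an estimated correlation), for example Cxcl10 (3.06 ± 0.34), Ifi44 (2.03 ± 0.26) and Ifitm3 (1.23 ± 0.15). Leukocyte adhesion genes rose in 4 of 10 (7 adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). Immediate early genes fell in 11 of 16 (median -0.85, adjusted p = 0.215 with an estimated correlation), including Jun (-1.05 ± 0.14) and Btg2 (-1.27 ± 0.15). Transporters fell in 6 of 23 (10 fell and 2 rose adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). Fibroblast markers rose in 6 of 11 beside the matrix genes (median 1.20, adjusted p = 0.450 with an estimated correlation). Microglia markers had a median of 0.93 with 0 of 17 past the limma test (adjusted p = 0.839 with an estimated correlation), and their mean level was 3.79 against 2.78 log2 units in controls. Directly between the stages, cell cycle (25 of 26) and interferon genes (21 of 24, adjusted p = 0.489 with an estimated correlation) rose and glucocorticoid targets fell (14 of 15, adjusted p = 0.0685 with an estimated correlation) from acute to subacute. Cell cycle genes fell again in 21 of 26 from subacute to chronic (median -1.80, adjusted p = 0.0110 with an estimated correlation). In subacute epilepsy 1509 genes were higher and 641 lower (1072 and 1107 with edgeR, 1262 and 1095 with quantile normalization). The total became 1141, 1401 and 1295 without subacute library 1, 2 or 3. At the chronic stage 6 were higher and 3 lower (7 and 7 with edgeR), and the total was 3 without control library 1, 412 without control library 3, 0 without chronic library 1 or 2 and 1 without chronic library 3. From subacute to chronic 222 genes rose and 458 fell, a total that was 318, 325 and 343 without subacute library 1, 2 or 3 and 383 and 348 without chronic library 1 or 3.

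In sorted spinal cord cells at the subacute stage of EAE, 6 of 10 leukocyte adhesion genes rose (adjusted p = 0.265 with an estimated correlation). The chemokine Cxcl9 rose from 1.36 ± 0.759 to 313 ± 231 CPM (6.87 ± 0.74, limma adjusted p = 0.000681, n = 3 per group), with Cxcl10 (3.27 ± 0.51). P-selectin, Selp, rose to 174 ± 56.5 from 3.89 ± 1.02 CPM (5.13 ± 0.39), E-selectin, Sele, to 456 ± 116 from 24.6 ± 19.3 (4.46 ± 0.68) and Vcam1 to 981 ± 145 from 233 ± 35.1 (2.07 ± 0.20). Vcam1 was also higher at the acute (457 ± 64.4 CPM, 0.97 ± 0.20, adjusted p = 0.0347) and chronic stages (763 ± 135 CPM, 1.70 ± 0.20, adjusted p = 0.00141). Ubd (5.82 ± 0.84) and Itih4 (4.59 ± 0.85) rose too. NF-kB targets rose in 10 of 22 (adjusted p = 0.278 with an estimated correlation), among them Tnfaip2 (2.79 ± 0.33) and the prostaglandin synthase Ptgs2 (1.91 ± 0.24). MHC class I genes rose in 5 of 11 (7 adjusted over the list alone, adjusted p = 0.265 with an estimated correlation) and class II genes in 4 of 5 (5 adjusted over the list alone, adjusted p = 0.278 with an estimated correlation), with Tap1 at 1.71 ± 0.30 and Cd74 at 34.4 ± 17.0 against 3.96 ± 1.81 CPM (2.76 ± 0.51). Cell cycle genes rose in 21 of 26 (24 rose and 1 fell adjusted over the list alone, median 1.89, adjusted p = 0.265 with an estimated correlation), for example Tpx2 (3.51 ± 0.39), Kif11 (3.30 ± 0.38) and Birc5 (2.28 ± 0.27). Matrix genes rose in 21 of 32 (27 adjusted over the list alone, median 1.81, adjusted p = 0.265 with an estimated correlation), including Mmp14 (2.47 ± 0.36) and the laminin Lamb1 (2.25 ± 0.41). Fibroblast markers had a median of 1.35 with 1 of 12 higher in the limma test (adjusted p = 0.603 with an estimated correlation).

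In subacute EAE barrier transporters fell in 7 of 23 (15 adjusted over the list alone, median -0.65, adjusted p = 0.278 with an estimated correlation), for example Slc22a8 (130 ± 25.6 against 448 ± 64.1 CPM, -1.78 ± 0.31), the thiamine carrier Slc19a3 (-1.43 ± 0.25) and Slc38a3 (-1.11 ± 0.19). Mfsd2a fell to 105 ± 7.12 from 257 ± 38.5 CPM (-1.28 ± 0.17, adjusted p = 0.000996), and was lower at the acute (-0.78 ± 0.17, adjusted p = 0.0415) and chronic stages (-1.08 ± 0.17, adjusted p = 0.00779). Wnt pathway genes fell in 4 of 18 (adjusted p = 0.470 with an estimated correlation), among them the Wnt deacylase Notum (-1.69 ± 0.36) and Tcf7 (-1.12 ± 0.29). Immediate early genes fell in 12 of 16 (13 adjusted over the list alone, median -0.98, adjusted p = 0.278 with an estimated correlation), with Egr1 at 1068 ± 106 against 3037 ± 556 CPM (-1.50 ± 0.26). Vwa3a (-2.33 ± 0.39), Fmo2 (-2.22 ± 0.36) and Ltbp4 (-2.14 ± 0.43) fell. Cldn5 (0.16 ± 0.17), Slc2a1 (-0.48 ± 0.26) and Cdh5 (0.17 ± 0.23) did not pass the test. At the chronic stage matrix genes were higher in 12 of 32 (24 adjusted over the list alone, median 2.16, adjusted p = 0.0903 with an estimated correlation) and NF-kB targets in 7 of 22 (14 adjusted over the list alone, adjusted p = 0.0903 with an estimated correlation). Fibroblast markers were higher in 3 of 12 beside them (10 adjusted over the list alone, median 2.44, adjusted p = 0.268 with an estimated correlation), at a mean level of 7.85 against 5.49 log2 units in controls. Mural markers were lower in 6 of 15 (8 adjusted over the list alone, median -0.93, adjusted p = 0.161 with an estimated correlation). With the mural level of each library as a covariate, 2 genes passed at the chronic stage in place of 357. From subacute to chronic, cell cycle genes fell in 18 of 26 (adjusted p = 0.131 with an estimated correlation). Of 14508 genes, higher and lower counts were 161 and 21 at the acute stage (108 and 63 with quantile normalization, 169 and 72 with edgeR, 8 and 2 without a filter on low values), 1170 and 516 at the subacute (981 and 1117, 1123 and 862, 798 and 274) and 273 and 84 at the chronic (319 and 202 with quantile normalization, 69 and 21 without a filter). They were 13 and 2 from acute to subacute (20 and 8 with quantile normalization, 3 and 2 with edgeR) and 5 and 86 from subacute to chronic (0 and 0 with the mural covariate). Without control library 1, 2 or 3 the totals were 11, 5 and 8 (acute), 752, 579 and 677 (subacute) and 91, 81 and 32 (chronic). Without the injured library 1, 2 or 3 they were 67, 5 and 466 (acute) and 635, 130 and 129 (chronic), and without subacute library 1 or 3 the subacute total was 801 and 711. Acute to subacute totals were 544, 1 and 1 without acute library 1, 2 or 3 and 0, 1 and 1 without the subacute ones. Subacute to chronic totals were 34 and 23 without subacute library 2 or 3 and 262, 13 and 0 without chronic library 1, 2 or 3.

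After stroke the subacute stage held the most called genes, with 20 of 31 matrix genes among those that rose. Osteopontin, Spp1, rose from 4.49 ± 1.47 to 233 ± 132 CPM (5.27 ± 0.36, limma adjusted p = 2.94e-06, n = 3 per group), the proteoglycan Dcn to 233 ± 116 CPM (4.38 ± 0.42), the collagen Col1a2 to 205 ± 104 CPM (4.21 ± 0.38) and Timp1 by 4.25 ± 0.33. Of the matrix genes 1 fell (23 rose and 1 fell adjusted over the list alone, median 1.88, adjusted p = 0.0496 with an estimated correlation). Fibroblast markers rose beside them in 8 of 11 (median 2.27, adjusted p = 0.0496 with an estimated correlation), from a mean level of 2.80 ± 0.23 to 5.35 ± 0.34 log2 units. Cell cycle genes rose in 13 of 23 (19 adjusted over the list alone, median 1.01, adjusted p = 0.0669 with an estimated correlation), with Top2a (3.13 ± 0.38) and Mki67 (2.82 ± 0.38). Hypoxia and glycolysis genes rose in 5 of 17 (median 0.23, adjusted p = 0.0496 with an estimated correlation), among them the hexokinase Hk2 (1.87 ± 0.28) and Vegfa (1.68 ± 0.29). NF-kB targets rose in 8 of 20 (11 adjusted over the list alone, adjusted p = 0.0669 with an estimated correlation), including Ccl2 (2.18 ± 0.33), and leukocyte adhesion genes in 4 of 10 (adjusted p = 0.146 with an estimated correlation), including the chemokine receptor Darc (3.93 ± 0.40). Fscn1 (2.69 ± 0.22), Pgf (2.44 ± 0.25) and Aplnr (2.95 ± 0.35), genes of sprouting vessels, rose, and so did the cystine carrier Slc7a11 (3.42 ± 0.48). Wnt pathway genes fell in 5 of 18 (15 adjusted over the list alone, median -0.52, adjusted p = 0.424 with an estimated correlation), for example Sox17 (-0.74 ± 0.14). Transporters fell in 4 of 23 (8 adjusted over the list alone, adjusted p = 0.360 with an estimated correlation), with Abcb1a at 814 ± 77.7 against 1175 ± 125 CPM (-0.53 ± 0.15). Neat1 (-1.60 ± 0.42) and Mgll (-1.60 ± 0.17) fell. At the acute stage Rsad2 (-1.42 ± 0.20), Egr2 (-0.91 ± 0.19) and the glucocorticoid target Tsc22d3 (-0.63 ± 0.13) were lower, and immediate early genes were lower in 2 of 16 (12 adjusted over the list alone, median -0.64, adjusted p = 0.651 with an estimated correlation). Cldn5, Slc2a1, Mfsd2a, Vcam1 and Pecam1 passed the test at 0 of 3 stages. From subacute to chronic, matrix genes fell in 21 of 31 (median -1.71, adjusted p = 0.0421 with an estimated correlation) and cell cycle genes in 15 of 23 (adjusted p = 0.0776 with an estimated correlation).

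In stroke libraries mitochondrial rRNA took 26.4 ± 4.03% of the reads in controls, 37.1 ± 1.18% at the acute, 35.8 ± 3.14% at the subacute and 34.4 ± 7.50% at the chronic stage. Of 13474 genes, 58 were higher and 134 lower at the acute stage (312 and 95 with mitochondrial rRNA left out before scaling, 126 and 145 with edgeR, 156 and 121 with quantile normalization, 12 and 11 without a filter on low values). In subacute stroke 493 were higher and 565 lower (917 and 234, 718 and 284, 695 and 378, and 467 and 226 in the same order). With the mural level of each library as a covariate the counts were 17 and 6 in acute and 666 and 2014 in subacute stroke. The median over all genes was -0.11 and -0.14 at these stages and 0.09 and 0.03 with mitochondrial rRNA left out. At the chronic stage limma called 0 genes, with 2217 genes at an unadjusted p under 0.05, 4 genes past the edgeR test and 2 with mitochondrial rRNA left out (median over all genes -0.15 and -0.01). The acute total was 22, 419 and 14 without control library 1, 2 or 3 and 64 and 54 without acute library 1 or 3. The subacute total was 427 and 394 without control library 1 or 3 and 614, 377 and 232 without subacute library 1, 2 or 3. The chronic total was 1361 without chronic library 1 and 1 without chronic library 3. Mitochondrial rRNA took 26.0% of the reads in chronic library 1 and 40.4 and 36.9% in chronic libraries 2 and 3. From acute to subacute 436 genes rose and 133 fell (302 in all without acute library 1, 366, 219 and 206 without subacute library 1, 2 or 3). From subacute to chronic 26 rose and 333 fell (117 and 121 without subacute library 2 or 3, 205 and 216 without chronic library 2 or 3).

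In acute TBI 16 of 32 matrix genes rose and 10 of 23 barrier transporters fell (adjusted p = 0.184 and 0.419 with an estimated correlation). Placental growth factor, Pgf, rose from 5.73 ± 1.01 to 69.8 ± 33.2 CPM (3.29 ± 0.32, limma adjusted p = 3.00e-05, n = 3 per group) and Timp1 by 3.33 ± 0.30. Adamts4 (113 ± 64.0 against 8.39 ± 5.15 CPM, 3.57 ± 0.53), Synpo (2.62 ± 0.29), Stc1 (2.20 ± 0.59) and Adamts9 (2.12 ± 0.40) rose. The chemokine Cxcl12 (560 ± 307 against 1445 ± 302 CPM, -1.48 ± 0.31), the vasoconstrictors Edn1 (-1.37 ± 0.16) and Edn3 (-1.37 ± 0.24) and Plekhh2 (-1.36 ± 0.29) fell. Adjusted over the list alone 23 matrix genes rose (median 0.92). Fibroblast markers rose beside them in 5 of 12 (9 adjusted over the list alone, adjusted p = 0.242 with an estimated correlation), at a mean level of 4.84 ± 0.63 against 3.67 ± 0.27 log2 units. Leukocyte adhesion genes rose in 5 of 11 (adjusted p = 0.242 with an estimated correlation), with Mcam (2.02 ± 0.25) and Selp (1.65 ± 0.19), and NF-kB targets in 6 of 20 (11 rose and 1 fell adjusted over the list alone, adjusted p = 0.242 with an estimated correlation), with Ch25h (1.80 ± 0.21) and the interleukin Il6 (2.53 ± 0.38). Angiogenesis genes rose in 5 of 22 (adjusted p = 0.525 with an estimated correlation), including Apln (1.68 ± 0.32). Transporters that fell (15 adjusted over the list alone, median -0.68) included Slc19a3 (134 ± 9.99 against 258 ± 3.30 CPM, -0.95 ± 0.16), Tfrc (-1.16 ± 0.23) and Slco1a4 (-1.02 ± 0.21). Cldn5 (-0.38 ± 0.14), Slc2a1 (-0.34 ± 0.27) and Vcam1 (-0.29 ± 0.23) did not pass the test. In subacute TBI cell cycle genes rose in 15 of 26 (20 rose and 1 fell adjusted over the list alone, median 1.11, adjusted p = 0.0835 with an estimated correlation), with Top2a (2.78 ± 0.28), Ccna2 (2.04 ± 0.25) and Bub1 (2.22 ± 0.28), n = 3 against 2. Matrix genes rose in 7 of 32 (27 adjusted over the list alone, adjusted p = 0.0835 with an estimated correlation). Fibroblast markers rose beside them in 2 of 12 (7 adjusted over the list alone, adjusted p = 0.277 with an estimated correlation), at a mean level of 5.52 ± 0.29 against 4.46 ± 0.67 log2 units. From subacute to chronic, cell cycle genes fell in 2 of 26 (16 adjusted over the list alone, adjusted p = 0.0598 with an estimated correlation).

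Mural marker levels differed between TBI acute-stage libraries, at 4.01 and 4.31 log2 units in control libraries 1 and 2 and 4.19 in acute library 3, against group means of 4.95 ± 1.38 and 5.58 ± 1.21. Of 14130 genes, 494 were higher and 275 lower at the acute stage, and 60 passed with these 3 libraries left out. The acute total of 769 became 357 and 345 without control library 1 or 2 and 295 and 458 without acute library 2 or 3. At the subacute stage 177 were higher and 15 lower (109 and 36 with edgeR, 178 and 81 with quantile normalization), in all 39 and 59 without control library 1 or 2 and 81 and 114 without subacute library 2 or 3. With the replicate number as a replicate block the subacute counts were 100 higher and 4 lower, and libraries of the same number correlated at 0.41 and 0.43 there. At the chronic stage limma and edgeR called 0 genes, with 481 genes at an unadjusted p under 0.05 (median over all genes 0.13, and 0.01 with mitochondrial rRNA left out). From acute to subacute 2 genes rose and 1 fell (137 in all without acute library 1, 41 without subacute library 1). From subacute to chronic 1 rose and 12 fell, in all 3 and 7 without subacute control library 1 or 2, 57 without subacute library 1, 2 and 3 without chronic control library 1 or 2, and 8 and 7 without chronic library 1 or 2.

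**Figure D2:**
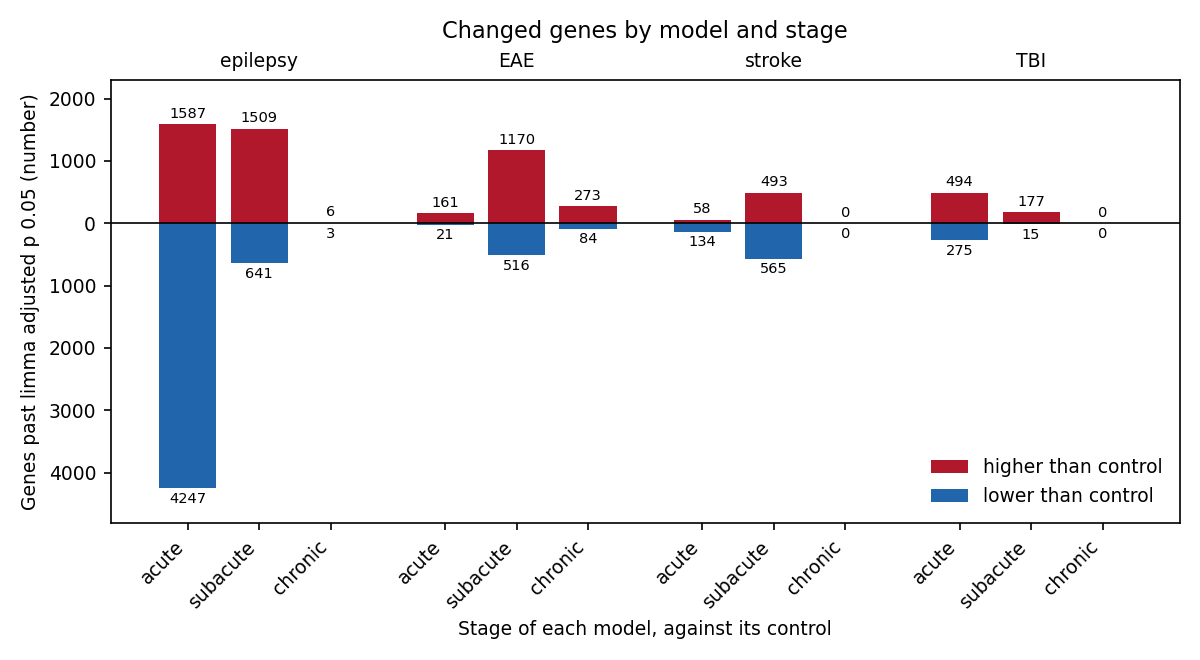
Number of genes past the limma test (adjusted p under 0.05) in each injured group against its control, with higher genes as red bars upward and lower genes as blue bars downward for 4 models and 3 stages (n = 3 per group, 2 for TBI subacute and chronic controls). The largest counts were 1587 higher and 4247 lower in acute epilepsy, and 0 genes passed in chronic stroke and chronic TBI.

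**Figure D3:**
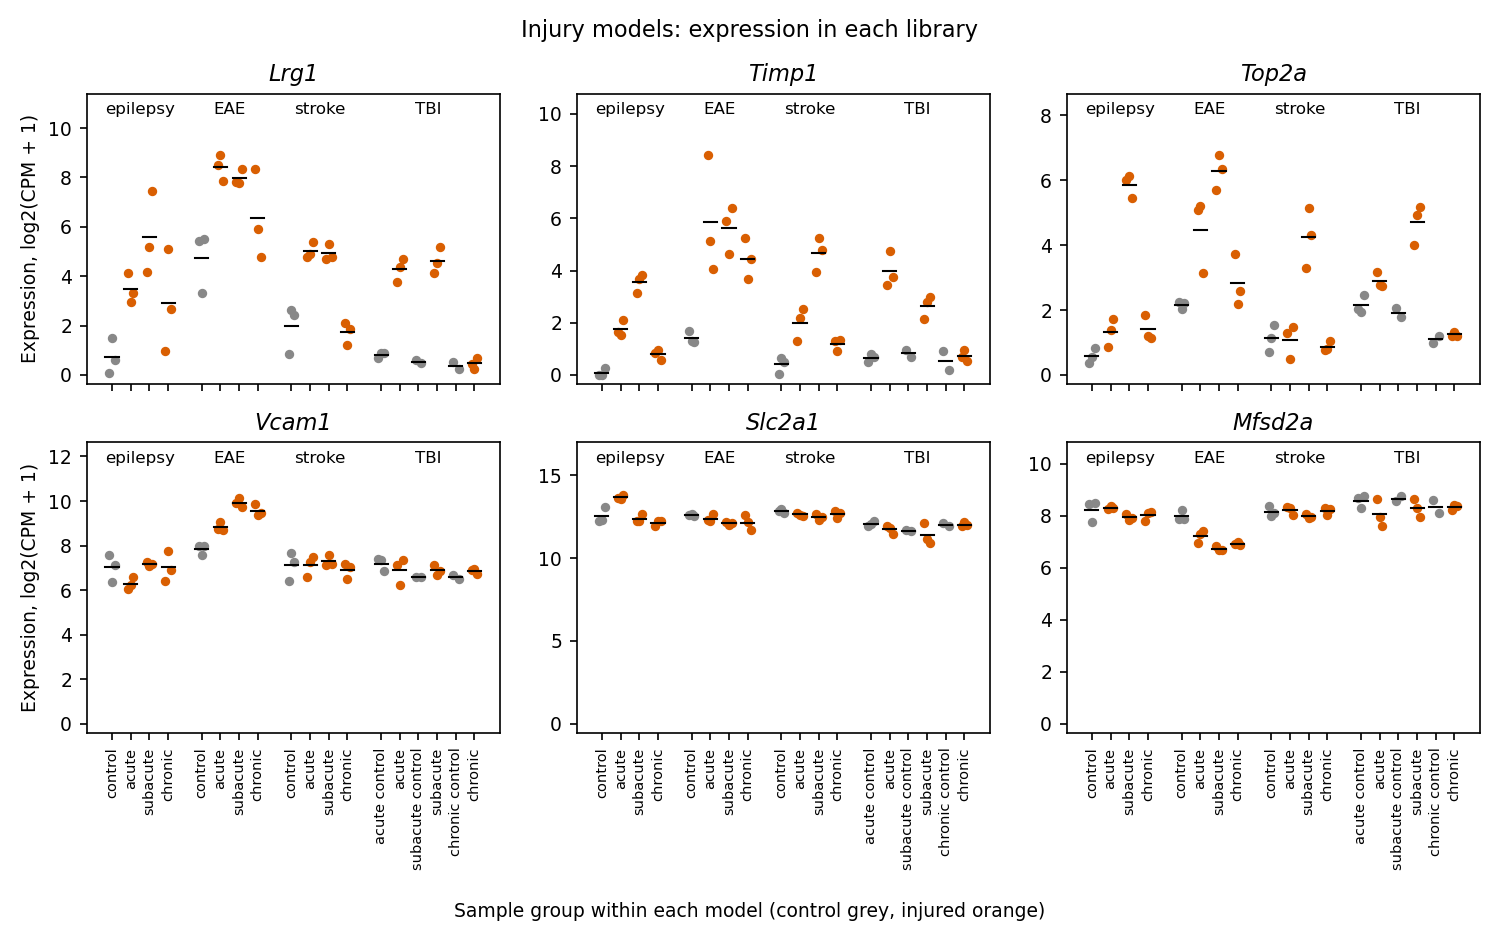
Levels of Lrg1, Timp1, Top2a, Vcam1, Slc2a1 and Mfsd2a in the injury models as log2(CPM + 1), with 1 point per library, a line at the group mean, controls in grey and injured groups in orange. Top2a rose by 5.27, 4.10, 3.13 and 2.78 log2 units at the subacute stage of epilepsy, EAE, stroke and TBI.

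**Figure D4:**
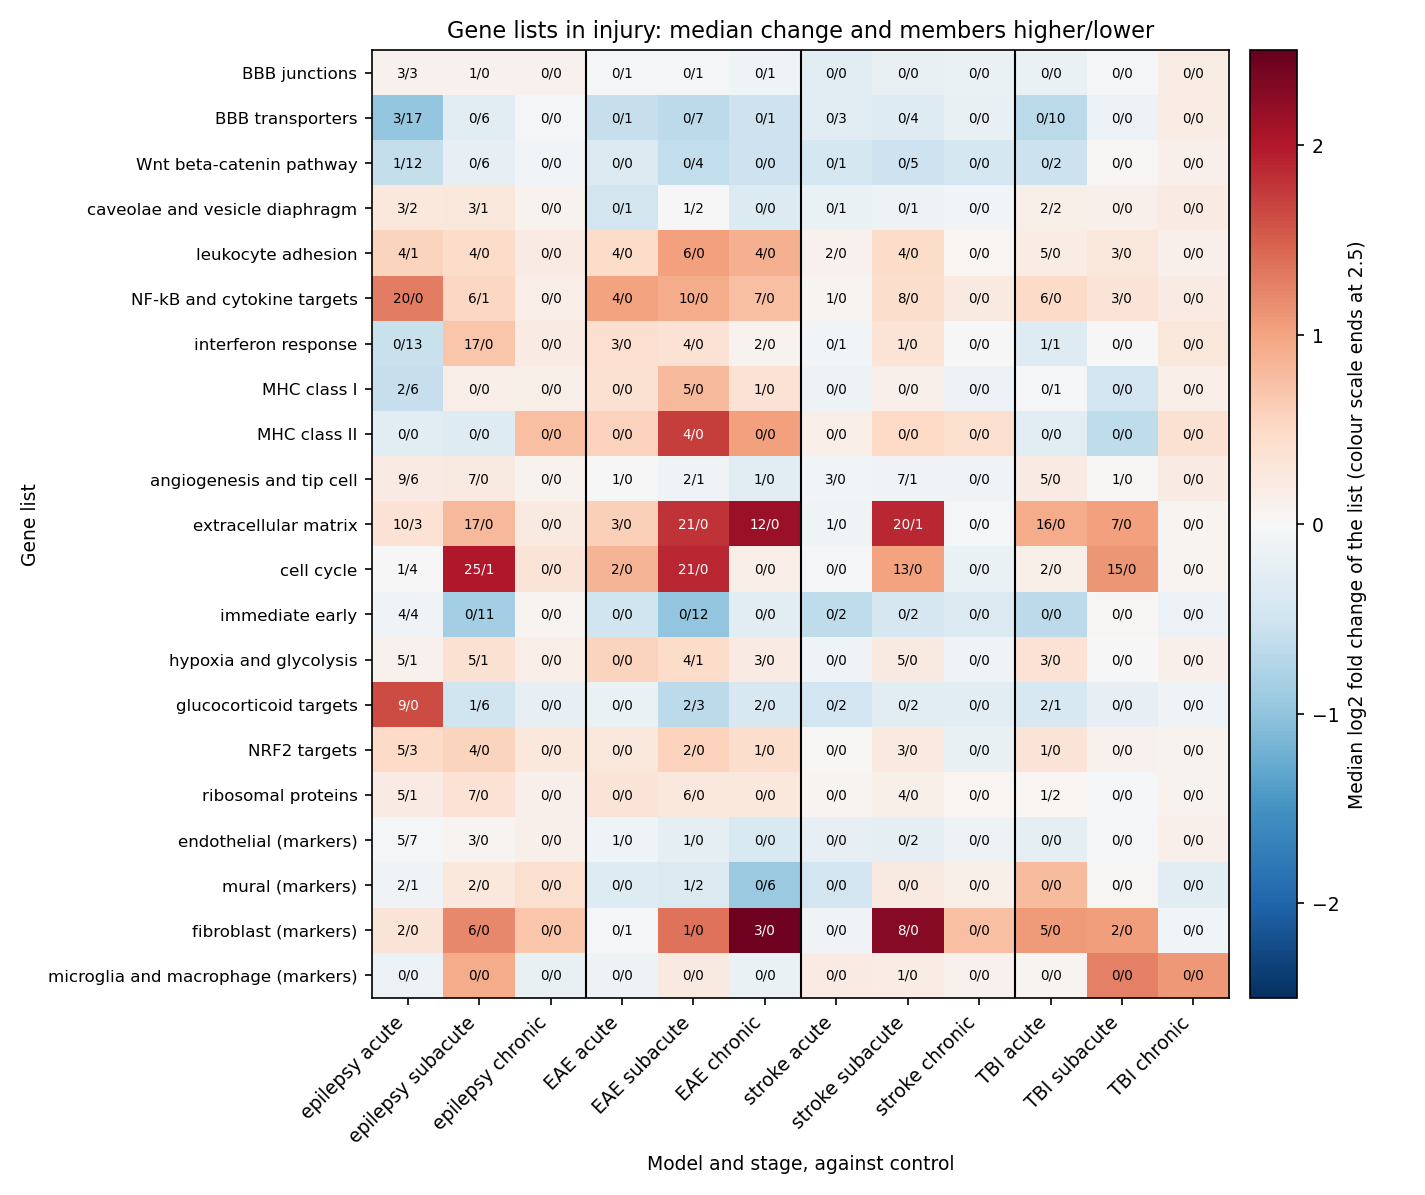
Median log2 fold of the measured members of 17 biology lists and 4 marker lists (lines) in the 12 comparisons of injured with control libraries (columns), with red for higher, blue for lower and the counts of higher and lower members past the limma test in each field. Cell cycle genes rose in 25 of 26, 21 of 26, 13 of 23 and 15 of 26 at the subacute stage of epilepsy, EAE, stroke and TBI, and the sign of some medians near 0, such as junction genes in acute epilepsy (0.11, and -0.08 with quantile normalization), turned with scaling.

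Some genes rose in several models at the same stage, each model against its own controls. The leucine-rich glycoprotein Lrg1 rose in all 4 models at the acute stage, by 2.75 ± 0.85 in epilepsy, 3.68 ± 0.74 in EAE, 3.04 ± 0.38 in stroke and 3.46 ± 0.26 in TBI. The metalloproteinase inhibitor Timp1 rose by 1.67 ± 0.26, 4.46 ± 0.83, 1.59 ± 0.33 and 3.33 ± 0.30 in the same order. Angpt2, Ecscr, Igfbp4, Sele and Upp1 were the other genes raised in all 4 at the acute stage. In 3 models each, Darc (mean log2 fold 2.87), Inhbb (2.56), Lcn2 (2.51) and Scgb3a1 (2.49) rose at the acute stage. Sgpp2 (mean -1.43), Edn3 (-1.38), Plekhh2 (-1.33), Tgfb2 (-1.30) and Alox12 (-1.26) fell in 3 models and Vwa3a (-1.27) in all 4. At the subacute stage Darc (mean 3.99), Top2a (3.82), Lrg1 (3.78), Mki67 (3.46) and Timp1 (3.44) rose in all 4 models, and Spp1 (3.77) in 3. Vwa3a (-1.51), Sytl1 (-1.16), Rasgrp2 (-1.08), Ltbp4 (-1.05) and Plekhh2 (-1.03) fell in epilepsy, EAE and stroke and did not pass in TBI. In 3 or more models, 50 genes rose at the acute stage (1.05 expected if models were independent), with 5 NF-kB targets and 3 angiogenesis genes among them, and 26 fell (1.11 expected). These expected counts, here and below, give every gene the same call rate within a model. Genes that are easy to call in every model can exceed them without a shared response. At the subacute stage 252 rose (7.75 expected) and 51 fell (1.14 expected), the raised ones with 16 cell cycle and 11 matrix genes. By the chronic stage 0 genes were shared, from limma calls of 9, 357, 0 and 0 genes in the 4 models, and 0 were shared with edgeR. Without a filter on low values 6 rose and 1 fell at the acute and 148 and 7 at the subacute stage. With replicate 1, 2 or 3 left out of all models, the raised counts were 17, 4 and 6 (acute) and 79, 27 and 52 (subacute), and the lowered counts 1, 0 and 2 (acute) and 14, 0 and 0 (subacute).

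The limma F test of a difference between the 4 log2 folds passed for 4968 of 15886 genes at the acute stage, 1185 at the subacute and 385 at the chronic. Of 100 permutations of labels within models, with the real labels as 1 of them, 2, 5 and 10 reached these counts, so chance was not excluded for the subacute and chronic counts. Such permutations can leave the effect in a model and remove it from another, so they are no clean measure of chance at any stage. Among the barrier and endothelial genes named before the data were examined, the test passed for Slc2a1 (adjusted p = 0.00158), Mfsd2a (0.0208), Vcam1 (0.00654), Cdh5 (3.27e-05) and Pecam1 (0.0120) at the acute stage. Slc2a1 stood at 1.12 in epilepsy against -0.21 in EAE and stroke and -0.34 in TBI, and Cdh5 at 1.32 against 0.15, -0.30 and 0.30. Mfsd2a and Vcam1 passed at the subacute (0.0182 and 0.00351) and chronic stages (0.0294 and 0.0130), the stages where chance was not excluded for the counts, with Vcam1 at 2.07 in subacute EAE against 0.15 in epilepsy, 0.18 in stroke and 0.29 in TBI. EAE was sampled from spinal cord and the other models from brain. The acute count was 2330 without replicate 2, the subacute counts 144, 76 and 458 without replicate 1, 2 or 3, and the chronic counts 12 and 57 without replicate 2 or 3.

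In acute and subacute epilepsy, EAE at each stage, acute and subacute stroke and acute TBI, more of the genes low in healthy brain endothelial cells rose than fell. More of the genes high in them fell than rose in the same comparisons. Both lists were chosen on the healthy libraries of this series, and are not independent evidence of their direction. Over all genes 161 rose and 21 fell in acute EAE, 1587 and 4247 in acute epilepsy and 58 and 134 in acute stroke. Fibroblast marker levels exceeded controls in subacute stroke (5.35 against 2.80 log2 units), acute TBI (4.84 against 3.67) and chronic EAE (7.85 against 5.49). They did not in acute EAE (5.21 against 5.49). Leaving out other cell markers only took the depleted list from 670 to 662 genes, so cell content was not separated from a change in endothelial cells. Acute epilepsy had the most called genes of the 12 comparisons of injured with control libraries, and neither list passed there with an estimated correlation: 193 of 414 enriched genes fell and 46 rose (adjusted p = 0.313 with an estimated correlation), and 114 of 590 depleted genes rose and 82 fell (adjusted p = 0.0599 with an estimated correlation). At the subacute stage 171 of 590 measured brain-depleted genes rose and 11 fell in epilepsy (median 0.42, adjusted p = 0.0112 with an estimated correlation), 204 of 628 rose and 6 fell in EAE (median 0.61, adjusted p = 0.0241 with an estimated correlation) and 117 of 570 rose and 10 fell in stroke (median 0.28, adjusted p = 0.00101 with an estimated correlation). In TBI 86 of 613 rose and 3 fell at the acute stage (adjusted p = 0.0150 with an estimated correlation) and 30 rose and 1 fell at the subacute (adjusted p = 0.126 with an estimated correlation). Brain-enriched genes fell in 94 of 414 and rose in 17 in subacute epilepsy (median -0.29, adjusted p = 0.0207 with an estimated correlation). They fell in 83 and rose in 7 of 416 in subacute EAE (median -0.48, adjusted p = 0.156 with an estimated correlation), in 62 and 8 of 420 in subacute stroke (median -0.37, adjusted p = 0.184 with an estimated correlation) and in 81 and 4 of 420 in acute TBI (median -0.40, adjusted p = 0.0960 with an estimated correlation). In subacute TBI 5 rose and 1 fell (adjusted p = 0.778 with an estimated correlation). With lists built on brain vascular cells, whose labels describe the preparation of the organ libraries, the adjusted p with an estimated correlation no longer passed in subacute epilepsy, EAE and stroke, at 0.0535 for the depleted list in epilepsy, 0.0532 in EAE and 0.0676 in stroke and 0.0535 for the enriched list in epilepsy. In TBI it was 0.0164 for the depleted list at the acute stage and 0.0155 at the subacute, where the main list had not passed. At the chronic stage 80 of 628 depleted genes rose and 5 fell in EAE (adjusted p = 0.0110 with an estimated correlation), and 4 enriched genes rose and 9 fell (0.165 as that adjusted p). In acute EAE 51 depleted genes rose and 0 fell, and 2 enriched genes rose and 8 fell (0.103 as that adjusted p for both lists). In acute stroke 17 depleted genes rose and 7 fell (0.193 as that adjusted p), and 2 enriched genes rose and 26 fell (0.299 as that adjusted p).

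**Figure D5:**
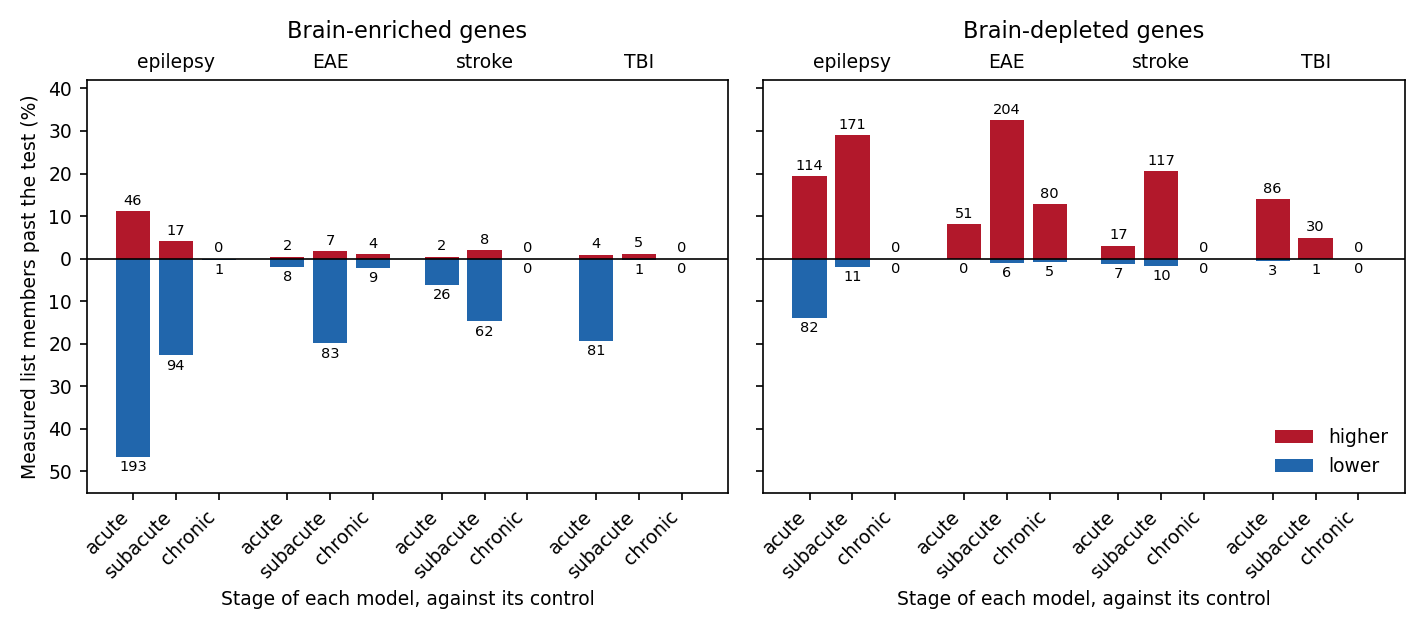
Percent of measured brain-enriched and brain-depleted genes, lists chosen on the healthy libraries of this series, that passed the limma test as higher (red, upward) or lower (blue, downward) in the 12 comparisons of injured with control libraries, with counts at the bars. In subacute EAE 204 of 628 depleted genes were higher and 83 of 416 enriched genes were lower.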

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

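In this part the tests of mural content, of the mitochondrial rRNA share and of the share of abundant genes were chosen only after the result was seen, and 1 condition for reading the fibroblast test was added after its values were seen, without changing any reading. Single results that stood out are given first. The Pecam1 level of 1 whole brain library lay apart from the other 3 with a gap of 0.847 of the range, and this was 1 of 24 such measures, of which about 1 in 20 would pass by chance. The limma test of a difference between the 4 models passed for 9 of 24 gene and stage pairs. The adjusted p-values were 0.00158 for Slc2a1, 0.0208 for Mfsd2a, 0.00654 for Vcam1, 3.27e-05 for Cdh5 and 0.0120 for Pecam1 at the acute stage, 0.0182 for Mfsd2a and 0.00351 for Vcam1 at the subacute, and 0.0294 for Mfsd2a and 0.0130 for Vcam1 at the chronic.

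Genes called in acute TBI fell from 769 to 60 when the 3 libraries with low mural marker levels were left out. With the mural level as a covariate 91.7% of the 769 genes were still called, which argues against mural content as the whole cause. The 9 choices of 2 control and 1 acute library to leave out, this one among them, gave 32 to 692 calls with a median of 235, so the 60 calls cannot be told apart from what fewer libraries in the fit would give, because other choices lay both above and below. The alternative grouping of the 6 libraries by low and high mural level called 503 genes against 769 for the real one. No biological explanation was tested, and differences in injury between animals stay open.

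Extracellular matrix genes rose in comparisons in which fibroblast markers were higher too (only 1 of 12 in subacute EAE), which may reflect fibroblasts sorted with the endothelial cells. The fibroblast marker level of each library was used as a covariate for the called matrix genes outside the marker list. Their median log2 fold was then 87.6% of its size in subacute epilepsy (1.31, median SE 0.24, to 1.15, SE 0.38, with 8 of 17 genes still called as the SE grew). It was 76.4% in subacute EAE (1.87, SE 0.43, to 1.43, SE 0.29, 17 of 21 still called), just above the bound set beforehand. It was 28.0% in subacute stroke (2.33, SE 0.33, to 0.65, SE 0.75, 0 of 20 still called) and 53.6% in acute TBI (1.39, SE 0.29, to 0.74, SE 0.38, 3 of 16 still called), where both fold and SE moved. In EAE marker levels of control and subacute libraries overlapped (4.57 to 6.15 and 5.52 to 7.49), and the result argues against the marker level as the whole cause. A mean of markers measures fibroblast content with error, so part of its effect can remain. In epilepsy the levels did not overlap (2.62 to 3.22 and 3.54 to 3.84). In subacute epilepsy, subacute stroke and acute TBI fibroblast content and a rise in endothelial cells cannot be told apart, because marker level and injury move together. After the sort the mean fibroblast marker level was 5.35 log2 units in subacute stroke and 4.84 in acute TBI. It was 2.80 and 3.67 in their controls and 3.34 in whole brain, so the sort cannot be taken to have removed fibroblasts. Chronic EAE and subacute TBI, where both groups were higher too, were not tested. A hypothesis is that endothelial cells themselves raise matrix genes in EAE, which single-cell data could test.

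More genes were called lower than higher in acute stroke and acute epilepsy. Every acute epilepsy library held less mitochondrial rRNA than any control, with a gap of -2.99 points, which argues against its share of the reads as the cause there, since a smaller share raises all other genes. Every acute stroke library held more than any control, with a gap of 4.80 points. Of the called genes 30.2% were higher in the main fit, 76.7% with the 2 genes left out, 46.5% with edgeR and 56.3% with quantile normalization. The excess of lower calls in acute stroke therefore depended on the scaling. Leaving the 2 genes out moves all others of a library alike. The rRNA share and a change in the cells cannot be told apart, because the share goes with injury. The 67 nuclear genes above 1000 CPM took 1.46 points more of the reads in the lowest acute than in the highest control epilepsy library. Their share lowers all other genes by -0.08 log2 units at most over pairs of an acute and a control library. The median difference of the other genes was -0.21 or lower in every pair. By bounds written after the result was seen, this argues against that share as the whole cause. A rise of genes below that level was not tested and stays open. A uniform fall of all transcripts after seizures would not lower CPM values, since each library is scaled to the same sum, so these data cannot address it.

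Other groupings of the libraries tested whether so many calls could arise by chance. With 10 splits of 6 libraries the lowest possible share is 0.1, so these splits are too few for a share under 0.05. Only the real split (1 of 10) reached the real count in these comparisons, given with the real count and the highest other: epilepsy acute 5834 and 0, subacute 2150 and 0, chronic 9 and 3, acute to subacute 6833 and 0, subacute to chronic 680 and 0, EAE acute 182 and 0, subacute 1686 and 0, chronic 357 and 0, subacute to chronic 91 and 0, stroke acute 192 and 69, subacute 1058 and 0, acute to subacute 569 and 0, subacute to chronic 359 and 0, and TBI acute 769 and 503. In chronic stroke all 10 splits reached the real count of 0, and the one joining control libraries 1 and 3 with chronic library 1 called 1211 genes. Mitochondrial rRNA took 24.5, 23.6 and 26.0% of the reads in these libraries. It took 31.0% in control library 2 and 40.4 and 36.9% in chronic libraries 2 and 3, so this split follows that share. From EAE acute to subacute 2 of 10 splits reached the real count of 15, and the one joining acute library 1 with subacute libraries 1 and 3 called 2096. That split follows the share as well, at 34.4, 26.5 and 19.8% in these libraries. The share was 12.2 and 14.8% in acute libraries 2 and 3 and 18.3% in subacute library 2. The 100 permutations of labels within models held the real labels as 1 of them. Only the real labels reached the real count for genes raised and for genes lowered in 3 or more models at the acute (50 and 26) and at the subacute stage (252 and 51), with 0 as the highest other. Permuting removes the effect from every model at once. This result therefore speaks against no effect in any model, and does not test whether unrelated responses share genes by chance. For changes that differ between models 2 of the 100, the real labels included, reached the 4968 of the acute stage (highest other 5626), 5 the 1185 of the subacute stage (3415) and 10 the 385 of the chronic stage (798), so chance is not excluded at the later 2 stages. A permutation can leave the effect in a model and remove it from another, which creates differences itself. These shares are therefore no clean measure of chance at any stage. All 100 reached the 0 genes shared by models at the chronic stage.

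For the brain endothelial libraries the labels describe a reporter mouse line, tamoxifen and a preparation that they do not describe for the others. No test separated this from organ within these libraries. With brain vascular cells, whose labels describe the same preparation as the organ libraries, 390 genes were enriched against 434 and 410 depleted against 670, 1 sort thus being swapped for another with more mural cells. Of the named genes against the mean of the organs, 64 kept their result, 9 became weaker, 2 stronger and 1 reversed. Enzyme digestion could raise immediate early genes such as Jun, whose log2 fold against the organs went from 1.32 to -0.41 (adjusted p = 0.392 in limma) in that setting. Whether digestion, reporter line, tamoxifen or cell sort sets these differences cannot be told apart, because each goes with the same 2 libraries.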

How the results depend on the processing

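Of the settings below, the edgeR test, the scaling without mitochondrial rRNA, the mural covariate, the low-mural TBI libraries left out and all settings of the stage contrasts were chosen only after the data were seen. Counts are genes called, and values that moved by over 1.5 times or whose test changed are given. Their cause was not tested, apart from the fall in acute TBI without the 3 low-mural libraries, treated above. A group left with 1 library was assumed to vary like the other groups. Without a filter on low values, counts were 0 (epilepsy chronic), 440 (epilepsy subacute to chronic), 10, 1072 and 90 (EAE acute, subacute, chronic), 0 (EAE acute to subacute), 23 and 693 (stroke acute, subacute), 443, 110 and 4 (TBI acute, subacute, chronic), 5 and 7 (TBI acute to subacute, subacute to chronic), 923 (brain vascular against endothelial), and for genes shared by models 6 raised and 1 lowered (acute) and 148 raised and 7 lowered (subacute). With quantile normalization they were 4 (epilepsy chronic), 28 (EAE acute to subacute) and 11 (TBI acute to subacute). Paired correlations of replicate numbers did not call for a replicate block in 10 of 12 comparisons. TBI subacute (0.41 and 0.43) and TBI chronic (0.15 and 0.25) were the exceptions. With the replicate number as a replicate block, counts were 3 (epilepsy chronic), 8 (EAE acute to subacute), 104 (TBI subacute), 8 (TBI subacute to chronic) and 885 (brain vascular against endothelial). With edgeR they were 14 (epilepsy chronic), 5 (EAE acute to subacute), 4 (stroke chronic), 5 (TBI acute to subacute) and 154 (change differs between models, chronic). With limma without a trend they were 90 (stroke acute), 9 (TBI acute to subacute) and 16 and 22 (genes lowered in 3 or more models, acute and subacute). With a pseudocount of 0.1 they were 8 (TBI subacute to chronic) and 180 (change differs between models, chronic). With mitochondrial rRNA left out they were 407 and 2 (stroke acute, chronic), 82 (genes raised in 3 or more models, acute) and 2220 (brain vascular against endothelial). With the mural covariate they were 1 (epilepsy chronic), 282 and 2 (EAE acute, chronic), 0 (EAE subacute to chronic), 23, 2680 and 35 (stroke acute, subacute, chronic), 195 (stroke acute to subacute), 304 (TBI subacute), 24 and 20 (TBI acute to subacute, subacute to chronic) and 8 (genes lowered in 3 or more models, acute). With only the 2 compared groups in the fit they were 1031 and 0 (epilepsy subacute, chronic), 64, 2937 and 1108 (EAE acute, subacute, chronic), 1964 and 3 (stroke subacute, chronic) and 179, 87 and 3 (TBI acute, subacute, chronic). With all 4 models in 1 fit they were 218 (epilepsy chronic), 1463, 3866 and 1664 (EAE acute, subacute, chronic), 39, 441 and 2 (stroke acute, subacute, chronic) and 113 (TBI subacute). Pooled TBI controls gave 1321 (acute) and 439 (subacute), and TBI acute had 60 with the 3 low-mural libraries left out. With brain vascular in place of brain endothelial cells 410 genes were depleted and Jun turned from 1.32 to -0.41. Median log2 folds of the enriched list built on those cells were 0.06 (epilepsy chronic), -0.24 and -0.13 (stroke subacute, chronic) and -0.04 (TBI subacute). Those of the depleted list were 0.11 and 0.11 (epilepsy acute, chronic), -0.06 and 0.18 (stroke acute, subacute), -0.13 in place of 0.01 (stroke chronic) and 0.42 and 0.14 (TBI subacute, chronic). The depleted list without markers of other cells kept a median of 0.09 in TBI chronic, where camera ranked it below other genes with an adjusted p of 0.0437 in place of 0.0566 (limma, adjusted p = 0.568 with an estimated correlation). On brain vascular cells the adjusted p of camera in limma became 0.535 for both lists in epilepsy chronic (0.00385 enriched and 0.00601 depleted before), 0.334 for the enriched list in stroke chronic (0.00950 before) and 0.00537 for it in TBI subacute (0.155 before). The adjusted p with an estimated correlation became 0.0535 for both lists in epilepsy subacute (0.0207 enriched and 0.0112 depleted before), and for the depleted list 0.0532 in EAE subacute (0.0241 before), 0.0676 in stroke subacute (0.00101 before), 0.805 in stroke chronic (0.0277 before) and 0.0155 in TBI subacute (0.126 before).

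With each library left out in turn, the lowest and highest counts were as follows. Against control they were 4868 to 6187, 1141 to 2954 and 0 to 412 (epilepsy acute, subacute, chronic), 5 to 466, 579 to 1876 and 32 to 635 (EAE), 14 to 419, 232 to 1091 and 0 to 1361 (stroke) and 295 to 1109, 39 to 248 and 0 to 0 (TBI). Between stages they were 5545 to 6160 and 318 to 479 (epilepsy acute to subacute and subacute to chronic), 0 to 544 and 0 to 262 (EAE), 206 to 753 and 117 to 356 (stroke) and 2 to 137 and 2 to 57 (TBI). Genes shared by models numbered 4 to 17 raised and 0 to 2 lowered (acute), 27 to 79 and 0 to 14 (subacute) and 0 to 0 (chronic), and genes whose change differed between models 2330 to 4090, 76 to 458 and 12 to 382 (acute, subacute, chronic). In healthy tissue the ranges were 360 to 846 enriched, 431 to 1225 depleted, 3280 to 6528 against the mean of the 4 organs, 9678 to 10372 against whole brain and 384 to 3435 between brain vascular and endothelial cells.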

Other observations

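Markers of other cell types differed between the healthy sorts, as a description of what each sort held. Against the mean of the 4 organs, brain endothelial cells had lower hepatocyte (7 of 9, 9 adjusted over the list alone), cardiomyocyte (5 of 7), kidney tubule (6 of 7) and lung epithelium markers (5 of 9, 7 adjusted over the list alone), with adjusted p of 0.397, 0.134, 0.489 and 0.489 with an estimated correlation. Each of these lists was highest in its own organ, with mean levels of 3.28 log2 units for hepatocyte markers in liver, 3.08 for cardiomyocyte markers in heart, 2.96 for tubule markers in kidney and 4.27 for epithelium markers in lung. Neutrophil markers were lower in 6 of 7 (adjusted p = 0.288 with an estimated correlation) and lymphocyte markers in 3 of 8 (6 adjusted over the list alone, 0.265 as that adjusted p). Red cell and platelet markers were higher in brain in 6 of 10 and lower in 1 (0.489 as that adjusted p). Mural (3 higher and 7 lower of 16), fibroblast (3 and 4 of 12), astrocyte (1 and 4 of 11), neuron (0 and 2 of 12) and oligodendrocyte markers (0 and 3 of 11) had no shift by camera.

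Some other lists and genes passed the test in the injury models. In subacute TBI astrocyte markers rose in 3 of 8 (adjusted p = 0.108 with an estimated correlation) and red cell markers fell in 2 of 10 (6 adjusted over the list alone, median -0.73, adjusted p = 0.0835 with an estimated correlation). In acute epilepsy the lung capillary genes Calcrl (-2.11 ± 0.17) and Car4 (-1.77 ± 0.16) fell, and Plat rose from 690 ± 306 to 2263 ± 471 CPM (1.80 ± 0.27). In acute TBI Car4 fell by -1.06 ± 0.19 and Ednrb rose by 1.41 ± 0.33. Calcrl, a receptor for adrenomedullin, rose in subacute EAE to 421 ± 51.0 from 217 ± 11.2 CPM (0.95 ± 0.16).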
